A study of Rattus norvegicus with 20 samples.

How the data were processed

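Alveolar type II epithelial cells from Sprague-Dawley rats were kept for 4 days on fibronectin-coated silastic membranes, on which they spread into monolayers with features of type I cells. Gene expression was then measured by 3' end RNA sequencing (QuantSeq, forward) in 20 libraries, 5 in each of 4 groups. Each library held RNA pooled from 4 technical replicate monolayers of 1 animal, and the replicate number gave the animal. Stretched cells (S) received 18 h of 0.01% DMSO and then 6 h of biaxial cyclic stretch at 15 cycles per min and a 25% change in surface area. Unstretched cells (NS) received DMSO for 24 h. The inhibitor groups, S_PI and NS_PI, received 1 µM GSK2606414, an inhibitor of the kinase PERK, on the same plan. No DMSO content is recorded for the inhibitor groups, so a match of vehicle with S and NS could not be checked. The series text gives 18 h of pretreatment and the treatment protocol 24 h for unstretched cells with inhibitor, which is 18 h plus the 6 h of the stretch period.

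The authors aligned the reads to the rat build rn6 with STAR and counted them per gene with HTSeq, per the submitters' processing notes; versions and gene annotation are not given in the sources used here. The authors deposited a table of raw counts for 17337 gene symbols in the 20 libraries. They also deposited a DESeq2 table, named as controlling for rat, whose values per the file headers are a mean of normalized counts, which has another unit than raw counts, a log2 fold change with its standard error, a Wald statistic, which is a score, and a p-value with its adjusted p-value. Its header does not say which groups were compared or in which direction, and several genes appear in it under more than 1 identifier, so it was read with 1 entry per symbol. Across genes its log2 values ran opposite to stretched over unstretched in the counts. Of the 17337 symbols, 8320 were tested; 7743 of these were in the RefSeq gene table, and 494 of them matched through a synonym.

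Counts assigned to genes ranged from 999209 to 3131541 per library. The HTSeq summary entries, which count alignment records and not genes, were left out of the gene counts. Records outside annotated genes made up 16.2 to 24.5% of all records, records that aligned to several places 35.5 to 57.7%. A count of 3, used as the detection floor, equals 0.958 to 3.00 CPM (counts scaled to a common library total) depending on the library. The labels name no molecular identifiers, so floors and counting intervals cover counting error only. No sequencing batch is given in the labels, so none could be tested.

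Genes were filtered with filterByExpr of edgeR on the 4 groups, scaled by TMM, and tested with the edgeR quasi-likelihood F test, with group and animal (as a block) in 1 fit to all 20 libraries, which left 12 residual degrees of freedom. The fit held no term for a stretch effect that differs between animals. Such differences thus entered the residual spread of every contrast, pooled with all other residual spread. That pooled spread can be too small for the stretch contrasts. For the inhibitor contrasts and the interaction it can be too wide. In the average stretch effect the 2 stretch pairs of an animal counted as independent. The contrasts were S vs NS, NS_PI vs NS, S_PI vs S, S_PI vs NS_PI and the interaction, which is the stretch effect with inhibitor minus that without it. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Standard errors are those of the fitted log2 fold changes, n = 5 animals per group, and CPM values are group means with SD. The average stretch effect over both inhibitor states was used to select genes for a second adjustment of the interaction test. That selection was planned, while the average stretch effect as a result of its own and the average inhibitor effect over stretched and unstretched cells were added after seeing the data. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

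Groups, tests, named genes, 17 pathway lists and 9 lists of cell type markers were fixed before the data were examined. The pathway lists cover PERK-ATF4 integrated stress response targets, ATF6 and XBP1 chaperone and ERAD targets, stress sensors and reported inhibitor targets, NF-kB and inflammatory mediators, immediate-early and MAPK response, YAP-TEAD targets, MRTF-SRF cytoskeletal targets, NRF2 antioxidant targets, heat shock response, cholesterol and fatty acid synthesis, hypoxia and glycolysis, epithelial junctions, p53 targets, apoptosis regulators, proliferation, extracellular matrix and TGF-beta response, and ion and water transport. The cell type lists cover alveolar type I, alveolar type II, transitional alveolar epithelial, macrophage and leukocyte, fibroblast and smooth muscle, endothelial, airway epithelial, mesothelial and red blood cell markers. Lists were tested against all other genes with camera of limma at its preset correlation of 0.01, adjusted over the 25 lists with tested members within each comparison. Of the 5 red blood cell markers, 0 were tested. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way without reference to other genes, were run beside it. Counts of list members are given over all genes tested and adjusted over the list alone.

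Named genes followed a fixed rule. In each comparison it took up to 10 genes per direction with the largest change among called genes with a mean of at least 10 CPM, a gene symbol and the same direction in at least 4 of the 5 animals. It added up to 4 members of each list with the smallest p and a fixed set of stress and alveolar genes. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. Genes that fall outside the rule are named as chosen after their values were seen.

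Single values per library, such as marker means, were compared between groups with two-sided exact paired permutation tests over the 5 animals, which cannot give a p below 0.0625. Correlations between comparisons are across genes, which are not independent replicates. For comparisons that share libraries, unchanged groups were simulated, and the covariance was computed again with the animals split so that no library served both comparisons. Other splits of the samples into groups were refitted 100 times per comparison. The alternatives were no animal block, only the compared groups, DESeq2, limma-voom, median-ratio, upper-quartile or library-size scaling, other count filters, a fold filter of 1.5, and leaving out each animal or library. Added after seeing the data were counts thinned to the smallest library, the test of whether the stretch effect differs between animals, and limma-voom for the interaction among stretch-responsive genes.

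The pipeline was tested on simulated data with 200 changed genes. In S vs NS it recovered 72.5% of 2-fold and 95.4% of 3-fold changes, in NS_PI vs NS 76.1% and 94.8%, in S_PI vs S 69.1% and 94.4%, and in the interaction 38.1% and 77.3%. Of 1.5-fold changes it recovered 27.6%, 23.1%, 23.9% and 6.09% in the same order. False calls made up 3.87 to 5.95% of calls. The simulated data held no stretch effect that differs between animals, and fewer changed genes than the stretch comparisons called. These shares may therefore not hold for the stretch contrasts. No pair of libraries agreed within counting error, with a lowest chi-square per degree of freedom of 2.65. A pair of unnamed columns of the authors' DESeq2 table was left out.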

Results

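Gene expression was measured by 3' end sequencing in rat alveolar epithelial monolayers, grown from type II cells into type I-like cells, under 4 conditions with 5 libraries each. Cells were left unstretched (NS) or stretched cyclically for 6 h (S), each also with the PERK inhibitor GSK2606414 (NS_PI and S_PI). PERK, encoded by Eif2ak3, is a sensor of protein folding stress in the endoplasmic reticulum, and it raises translation of the transcription factor Atf4. Libraries held 999209 counts (S, animal 4) to 3131541 counts (S, animal 2), with group means of 1810920 in NS, 1892630 in S, 1923080 in NS_PI and 1633310 in S_PI. Depth of stretched minus unstretched cells without inhibitor was 81714 ± 707656 counts (mean and SD of paired differences, two-sided exact paired permutation p = 0.812). With inhibitor it was -289772 ± 376392 counts, higher in 1 of 5 animals (exact paired permutation p = 0.188). With 5 animals this test cannot show that depth was balanced. The median standard error of a log2 fold change was 0.20, which gives a 95% confidence interval of about 0.44 to each side, and about 0.63 for the interaction.

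Animal and stretch accounted for most of the variation between libraries. The animal accounted for 47.0% of the variance over all genes, stretch for 22.7% and the inhibitor for 2.21%. These shares were not set against those that unchanged groups would give, so the 2.21% alone does not show an inhibitor effect. Deviations from group means correlated across genes with a median r of 0.48 between libraries of the same animal and -0.17 between those of different animals. Of 20 libraries, 20 correlated best with their own animal. The first principal component (26.5% of variance) followed the animal, which accounted for 92.7% of it. The second (24.5% of variance) followed stretch (85.5% of it) and was lower in the stretched library of 5 of 5 animals without inhibitor and 5 of 5 with it.

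**Figure D1:**
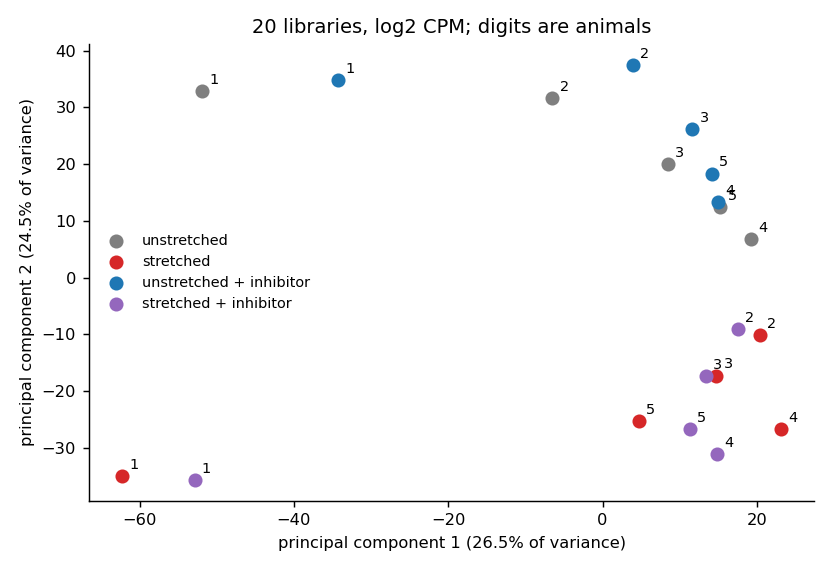
The first 2 principal components of log2 CPM (26.5% and 24.5% of variance) for the 20 libraries, with colour for group and digits for animal. The 4 libraries of animal 1 lie apart at the low end of the first component, and stretched libraries lie lower on the second than the unstretched library of the same animal.

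S vs NS asked what 6 h of cyclic stretch changes in these cells. Stretch changed 2075 of 8320 tested genes (24.9%), 1044 up and 1031 down. At least 2-fold changes made up 242 of the rises and 359 of the falls. Csrnp1 (ENSRNOG00000033433), which encodes a nuclear protein rich in cysteine and serine, rose 9.34-fold, from 31.7 ± 5.79 to 312.4 ± 123 CPM (mean ± SD, n = 5). Serpinb2, an inhibitor of plasminogen activators, rose 8.24-fold in 5 of 5 animals. The transcription factors Klf4 and Fosl1 rose 6.07-fold and 5.42-fold, and Il11, a cytokine of the interleukin 6 family, 5.47-fold, each in 5 of 5 animals. The collagenase Mmp13, the hyaluronan-binding factor Tnfaip6, the chemokines Cxcl2 and Ccl3 and the membrane protein Emp1 completed the 10 largest rises among genes with a mean of at least 10 CPM. Their log2 fold changes were 2.08 to 2.29. Ankrd1 (ENSRNOG00000018598), a nuclear ankyrin repeat protein and target of YAP, fell by 2.93 ± 0.27 (SE) on the log2 scale, from 1199.7 ± 769 to 153.5 ± 83.8 CPM.

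Tuba8, a tubulin gene, fell by 3.26 ± 0.29, to 2.22 CPM in stretched cells, which lies within the range of the detection floor of 0.958 to 3.00 CPM. Scnn1g, the gamma subunit of the epithelial sodium channel, fell by 2.69 ± 0.44, the transcription factor Cebpd by 2.13 ± 0.16, the chemokine Ccl1 by 2.43 and Dcdc2 by 2.42, each in 5 of 5 animals. The remaining genes with the largest falls were Trim63, a ubiquitin ligase, Sgcd, a sarcoglycan, Prorsd1 and Akap5, an anchor of protein kinase A. Their log2 changes were -1.98 to -1.95, and Trim63, Sgcd and Akap5 were lower in 4 of 5 animals. The call of Sgcd (adjusted p = 0.0273) was not kept with DESeq2 (adjusted p = 0.0812) or without animal 1 (0.0684), 3 (0.147) or 4 (0.0639). Its adjusted p ranged from 0.00154 to 0.183 over its alternatives. Without animal 2, 665 genes fell, and without animal 3, 656. Without animal 1, 1784 genes passed.

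Among targets of the PERK-ATF4 integrated stress response more rose than fell with stretch. Of 32 measured members 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 change of 0.40. The camera adjusted p was 0.000244, and adjusted p = 0.353 with an estimated correlation. Atf4 itself (ENSRNOG00000017801) rose by 0.97 ± 0.15, from 1491.5 ± 359 to 2935.8 ± 768 CPM, in 5 of 5 animals (adjusted p = 0.00011). Ppp1r15a, a regulatory subunit of the phosphatase of eIF2α, rose by 1.98 ± 0.25, the transcription factor Ddit3 (CHOP) by 0.84 ± 0.14 and Slc7a1, a transporter of cationic amino acids, by 0.91 ± 0.17. Asns, which encodes asparagine synthetase, had a log2 change of -0.16 ± 0.23, which was 0.15 without animal 2 and 0.02 without animal 3. Trib3, a pseudokinase gene induced by ATF4, had one of 0.46 ± 0.20 (adjusted p = 0.0895), which passed without animal 3 (0.73, adjusted p = 0.0201; 0.0201 to 0.614 over its alternatives). Eif2ak3 itself had a log2 change of 0.32 ± 0.22 (adjusted p = 0.295), and it passed without animal 1 (0.58, adjusted p = 0.00779; 0.00779 to 0.650 over its alternatives).

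The other arms of the response to protein folding stress in the endoplasmic reticulum did not move together. Of 26 measured ATF6 and XBP1 targets, which are chaperones and factors of protein degradation, 2 rose and 0 fell (2 and 0 adjusted over the list alone). Their median was -0.04, their mean 0.01 and the test upward (camera adjusted p = 0.864). The 2 were Herpud1, which acts in that degradation and rose 2.47-fold, and Dnajb9, a cochaperone, with a log2 change of 0.54 ± 0.16. Dnajb9 did not pass without animal 3 (adjusted p = 0.0649), without animal 5 (0.0578) or with library size as the only scaling (0.0542; 0.00521 to 0.0828 over its alternatives). Hspa5, the main chaperone of the endoplasmic reticulum, had a log2 change of -0.18 ± 0.17 at 9140.4 CPM in unstretched cells. Atf6 had one of 0.25 ± 0.21 and Xbp1 one of -0.02 ± 0.23, whose sign turned under 7 alternatives. Ern1, at a mean of 0.643 CPM, was below the filter. Of 8 stress sensors and reported inhibitor targets, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.866).

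The lists of immediate-early, heat shock and hypoxia genes were higher by camera, and that of lipid synthesis was lower. Of 34 immediate-early and MAPK response genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.82. The camera adjusted p was 8.84e-12, and adjusted p = 0.0780 with an estimated correlation. Nr4a2, a nuclear receptor, rose by 1.81 ± 0.21 and Dusp2, a phosphatase of MAP kinases, by 1.71 ± 0.21. Of 19 heat shock genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 8.43e-05; adjusted p = 0.164 with an estimated correlation). The chaperones Hspa1a and Hspb1 rose by 1.76 ± 0.23 and 0.69 ± 0.17. Of 22 hypoxia and glycolysis genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 4.57e-05; adjusted p = 0.163 with an estimated correlation). Ndrg1 rose by 1.07 ± 0.17, the glycolytic enzyme Aldoa by 0.61 ± 0.14 and the angiogenic factor Vegfa by 0.59 ± 0.13. Of 19 genes of cholesterol and fatty acid synthesis, 13 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.77. This call also held with an estimated correlation (camera adjusted p = 2.06e-10 and 0.0297). Fdft1, squalene synthase, fell by 1.75 ± 0.17, and Hmgcs1, which makes the precursor of mevalonate, fell by 1.41 ± 0.14, from 358.0 ± 74.3 to 133.3 ± 16.4 CPM.

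**Figure D2:**
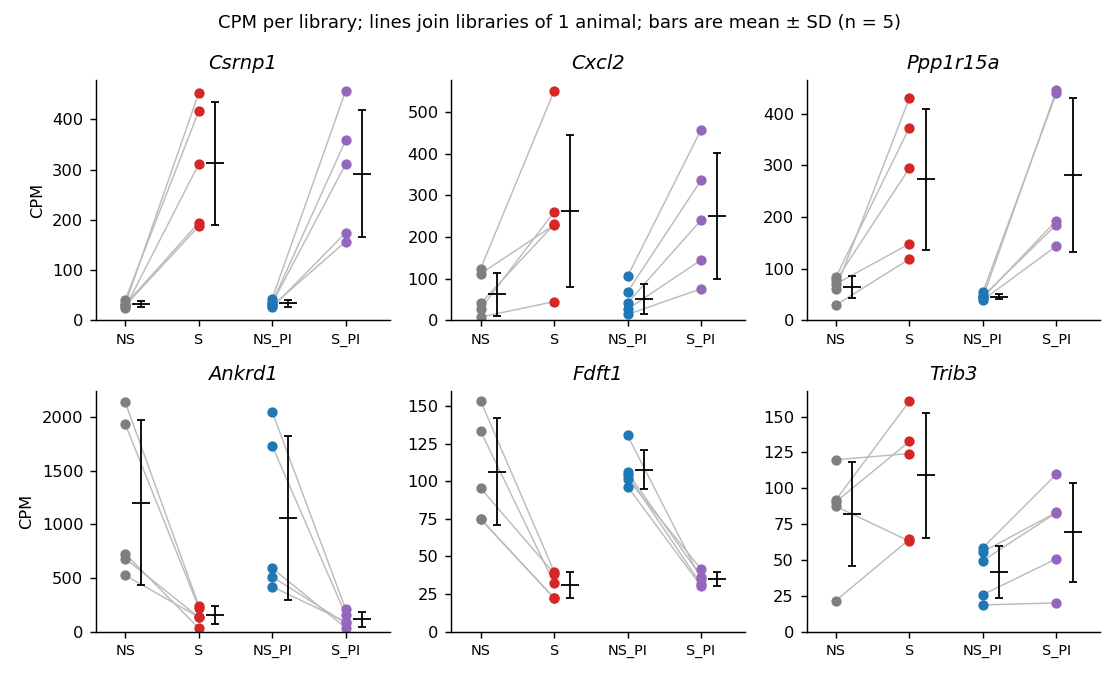
CPM (linear axes from 0) of Csrnp1, Cxcl2, Ppp1r15a, Ankrd1, Fdft1 and Trib3 per library in the 4 groups, with lines joining stretched and unstretched libraries of 1 animal and black bars for mean ± SD (n = 5). Csrnp1 averaged 31.7 CPM in NS and 312.4 in S, and Ankrd1 1199.7 and 153.5.

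Among inflammatory mediators more rose than fell, and the list of leukocyte markers was higher by camera. Of 28 NF-kB and inflammatory genes, 10 rose and 2 fell (10 and 3 adjusted over the list alone), with a median of 0.46. The camera adjusted p was 0.0114, and adjusted p = 0.393 with an estimated correlation. Cxcl2, a chemokine for neutrophils, rose by 2.23 ± 0.24 and Ptgs2, the inducible cyclooxygenase, by 2.44 ± 0.44 from 2.47 CPM, near the floor. Csf1, a growth factor of macrophages, fell by 1.33 ± 0.14 and the transcription factor Irf1 by 1.29 ± 0.19. Of 15 macrophage and leukocyte markers, 6 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00339; adjusted p = 0.232 with an estimated correlation). Their mean was higher in stretched cells in 5 of 5 animals, by 0.39 ± 0.11 (SD of the paired log2 differences; two-sided exact paired permutation p = 0.0625, the smallest that 5 animals allow). Fcer1g and Tyrobp, signalling adaptors of myeloid cells, rose by 0.91 ± 0.16 and 0.63 ± 0.14, and Laptm5, a lysosomal membrane protein of leukocytes, rose by 0.62 ± 0.14. Of these 15 markers, 0 were in another list.

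The lists of type I markers and junction genes were lower by camera. Of 16 alveolar type I markers, 6 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.43. The camera adjusted p was 0.0180, and adjusted p = 0.469 with an estimated correlation. Their mean was lower in 5 of 5 animals, and averaged over both inhibitor states it changed by -1.66 in animal 1 and by -0.66 to -0.14 in the others. Cldn18, an alveolar claudin, fell by 0.92 ± 0.26 (adjusted p = 0.0141), a call lost without animal 5 (0.0912; 0.00117 to 0.314 over its alternatives). Pdpn, a membrane protein of type I cells, had a log2 change of -0.42 ± 0.17 (adjusted p = 0.0769), and it passed with upper-quartile scaling (0.0377) or library size alone (0.0189; 0.0189 to 0.780 over its alternatives). Aqp5, a water channel of type I cells, was below the filter at a mean of 3.1 CPM. Of 19 junction genes, 4 fell and 0 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.0172; adjusted p = 0.423 with an estimated correlation). Crb3, a polarity gene, fell by 1.20 ± 0.27 and Gja1, connexin 43, fell by 0.97 ± 0.23. Averaged over both inhibitor states, the list changed by -1.11 in animal 1 and by -0.64 to 0.07 in the others. The junction call was lost without animal 4 (adjusted p = 0.0785) or animal 5 (0.0568; 0.00103 to 0.423 over its alternatives).

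The list of proliferation genes was higher by camera, with 7 of 27 up and 0 down (8 and 0 adjusted over the list alone; camera adjusted p = 0.00888; adjusted p = 0.329 with an estimated correlation). Pcna, the clamp of DNA polymerase, rose by 0.78 ± 0.15 and Ccnb1, cyclin B1, by 0.97 ± 0.25. The list of 20 MRTF-SRF cytoskeletal targets had 9 members that fell and 1 that rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.0606). The actin-binding proteins Tagln and Tpm1 had log2 changes of -1.03 ± 0.15 and -0.75 ± 0.14. Of 16 YAP-TEAD targets, 3 fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.106), among them Ankrd1 and the matricellular protein Cyr61, with -1.47 ± 0.19. Of 22 NRF2 antioxidant targets, 8 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.0606), among them the quinone reductase Nqo1 with 0.85 ± 0.22. Of 27 matrix and TGF-beta response genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.05004). The growth factor Tgfb1 rose by 1.00 ± 0.19 and the protease inhibitor Timp1 by 0.75 ± 0.15.

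The other lists were not called by camera. Fry, which does not refer to other genes, called p53 targets and apoptosis regulators lower and airway markers higher, and of the lists above without a camera call the MRTF-SRF and YAP-TEAD lists lower and the NRF2 and matrix lists higher. Of 15 type II markers 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.418), among them the transcription factor Cebpa with 0.87 ± 0.15. Sftpc, surfactant protein C, had a log2 change of -0.35 ± 0.47, which was 0.04 without animal 1. Of 12 markers of transitional alveolar cells 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.418). Their median was -0.02, while their mean, 0.25, and the test pointed up, and the keratin Krt8 fell by 0.79 ± 0.15. Of 19 p53 targets 2 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.152), and of 21 apoptosis regulators 4 rose and 4 fell (4 and 4 adjusted over the list alone; 0.529). Of 15 ion and water transport genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; 0.987), with a median of 0.09 while the mean, -0.14, and the test pointed down. Among other cell types, 2 of 11 fibroblast and smooth muscle markers rose (1 adjusted over the list alone; camera adjusted p = 0.378), and 1 of 4 airway markers rose (1 adjusted over the list alone; 0.418). Of 4 endothelial markers 1 fell (1 adjusted over the list alone; 0.588) and 1 of 3 mesothelial markers rose (2 rose and 1 fell adjusted over the list alone; 0.588). That mesothelial marker was Msln, with 0.82 ± 0.24, which stood at 2.30 in animal 1 and at 0.19 to 0.48 in the others. Its call was lost with only the compared groups (adjusted p = 0.0734) and without the animal as a block (0.115; 0.00255 to 0.115 over its alternatives). Of 5 red blood cell markers 0 were tested.

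Against the authors' deposited table, 937 genes with adjusted p below 0.05 there were also tested here, 534 higher and 403 lower in stretched cells with the sign of the table reversed. Of these, 932 were also called here in the same direction and 0 had the opposite sign. Among all matched genes 2035 were called here. The direction of the deposited table was read from these counts, so the match in sign is not independent. Log2 changes correlated across 8176 genes with r = 0.989 between the authors' deposited table, sign reversed, and S vs NS. With library size as the only scaling the median log2 change of all genes was -0.12 in S vs NS, and 722 genes rose and 1425 fell. Changes are given relative to the TMM scale. Without the animal as a block 818 genes passed, and with only the compared groups 1048. Without the block the type I, junction, leukocyte and NF-kB calls were lost (adjusted p = 0.279, 0.0632, 0.0632 and 0.0946), as was the type I call with fry (0.0656). Over the alternatives, adjusted p reached at most 0.469, 0.423, 0.232 and 0.393 in these lists and at least 0.00228, 0.00103, 0.00120 and 0.00114.

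S_PI vs NS_PI asked what stretch changes in the presence of the PERK inhibitor. With inhibitor, stretch changed 2534 of 8320 genes (30.5%), 1263 up and 1271 down. At least 2-fold changes made up 333 of the rises and 480 of the falls. Fosl1 (ENSRNOG00000020552) rose 13.7-fold, from 2.04 ± 1.04 CPM, near the floor, to 28.6 ± 9.23 CPM (mean ± SD, n = 5). Serpinb2 rose 11.7-fold, Csrnp1 8.32-fold, Il11 6.64-fold and Klf4 by 2.81 on the log2 scale, each in 5 of 5 animals. Mmp13, Hspa4l, a heat shock protein, Tnfaip6, the opioid precursor Penk and the growth factor Bmp2 followed, with log2 fold changes of 2.64 to 3.32. Tnfaip6 stood at 5.10 in animal 1 and at 2.13 to 2.52 in the others. Ccl1 fell by 3.38 ± 0.38, Scnn1g by 3.17, Ankrd1 by 3.16 and Atp12a, a proton pump, by 2.83. Pik3ip1, Ackr3, Acta1, Rtp4, Dcdc2 and Cebpd followed, with log2 changes of -2.76 to -2.20.

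The PERK-ATF4 list was also higher with stretch by camera in the presence of the inhibitor. Of 32 members 21 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 0.72. The camera adjusted p was 3.25e-11, and adjusted p = 0.112 with an estimated correlation. Atf4 rose by 1.26 ± 0.15, from 1204.9 ± 203 to 2945.5 ± 619 CPM. Ppp1r15a rose by 2.50 ± 0.26, Slc7a1 by 1.46 ± 0.17, Ddit3 by 0.94 ± 0.14 and Atf3, a transcription factor, by 1.34 ± 0.18. Eif2ak3 rose by 0.85 ± 0.22 (adjusted p = 0.00565), and Trib3 and Atf6 rose by 0.69 ± 0.21 and 0.74 ± 0.21. The calls of Trib3 and Atf6 were lost without animal 4 (adjusted p = 0.0770 and 0.0758; ranges over their alternatives 0.00226 to 0.289 and 0.00545 to 0.153). Of 26 ATF6 and XBP1 targets 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.926), with a median of -0.05 and an upward test. Hspa5 and Xbp1 had log2 changes of -0.22 and 0.11.

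With inhibitor as well, stretch raised the list of immediate-early genes and lowered that of lipid synthesis by camera. Of 34 immediate-early genes 21 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 1.18. Of 19 genes of cholesterol and fatty acid synthesis 15 fell and 0 rose (15 and 0 adjusted over the list alone), with a median of -0.94. Both calls held with an estimated correlation (camera adjusted p = 1.19e-14 and 1.32e-10; adjusted p = 0.0400 and 0.0237 with an estimated correlation). Nr4a2 rose by 2.35 ± 0.22, while Sqle, squalene epoxidase, fell by 1.21 ± 0.16 and Fdft1 by 1.63 ± 0.17. Hypoxia genes (9 of 22 rose), heat shock genes (9 of 19), proliferation genes (8 of 27) and NRF2 targets (7 of 22) were higher as lists by camera, with 0 members that fell and 9, 10, 8 and 7 that rose adjusted over the list alone. Their camera adjusted p were 1.56e-05, 0.000599, 0.00214 and 0.00413, and adjusted p = 0.112, 0.187, 0.192 and 0.192 with an estimated correlation. Vegfa rose by 1.15 ± 0.13 and Gclc, an enzyme of glutathione synthesis, by 1.21 ± 0.19, each in 5 of 5 animals.

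Of 28 NF-kB and inflammatory genes 12 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.0192; adjusted p = 0.430 with an estimated correlation). The cytokine Il1b rose by 1.82 ± 0.27 and Csf1 fell by 1.68 ± 0.14. Of 15 leukocyte markers 8 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00395; adjusted p = 0.192 with an estimated correlation). Their mean was higher in 5 of 5 animals, by 0.47 ± 0.24 (SD of paired differences). Of 16 type I markers 9 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.00373; adjusted p = 0.414 with an estimated correlation). Of 19 junction genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0129; adjusted p = 0.430 with an estimated correlation). Pdpn fell by 0.47 ± 0.17 in 4 of 5 animals (adjusted p = 0.0393), a call lost without animal 1, 4 or 5 (0.131, 0.162 and 0.0976; 0.0107 to 0.630 over its alternatives). Without animal 1 the junction and NF-kB calls were lost (adjusted p = 0.0632 and 0.102; 0.00119 to 0.430 and 0.00321 to 0.430 over their alternatives). Without the animal as a block 1229 genes passed, and the type I, junction, leukocyte and NF-kB calls were lost (adjusted p = 0.230, 0.0636, 0.0517 and 0.0966). Over the alternatives the type I and leukocyte lists ranged from 0.000226 to 0.414 and from 0.000467 to 0.192. With upper-quartile scaling 1030 genes rose and 1612 fell, and with library size alone the median of all genes was -0.12.

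**Figure D3:**
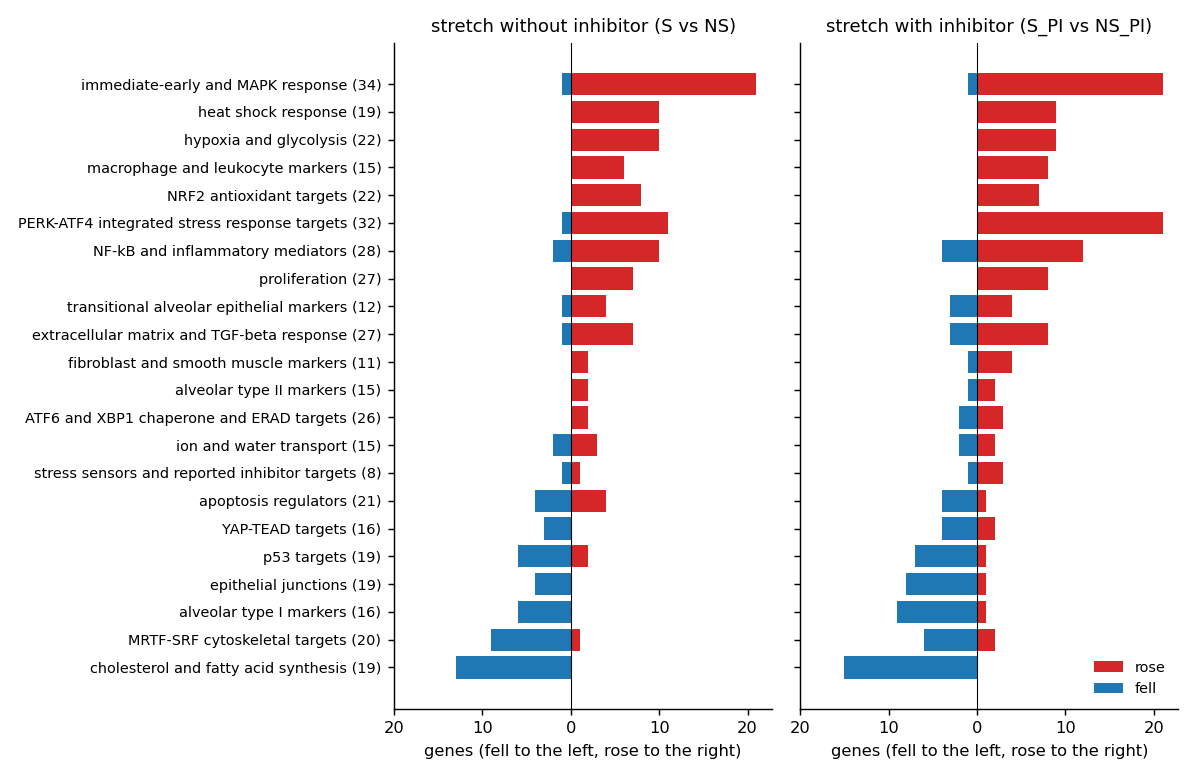
Number of genes of each list with at least 8 measured members (measured number in brackets) that rose (red, to the right) or fell (blue, to the left) with stretch without inhibitor and with it. PERK-ATF4 targets had 11 that rose without inhibitor and 21 with it, and cholesterol and fatty acid synthesis 13 and 15 that fell.

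NS_PI vs NS asked what the inhibitor changes without stretch. The list of PERK-ATF4 targets was lower with inhibitor, with 30 of 32 members below 0 and a median log2 change of -0.57. This call held with an estimated correlation (camera adjusted p = 7.65e-33 and 0.0112). Slc7a1 had a log2 change of -0.95 ± 0.17, from 172.2 ± 43.7 to 88.9 ± 23.7 CPM, below 0 in 5 of 5 animals (adjusted p = 0.133). Trib3 had one of -0.98 ± 0.21 (5 of 5 animals below 0), and Cth, an enzyme of cysteine synthesis, one of -1.81 ± 0.40 (4 of 5). Nars, a transfer RNA synthetase, had one of -0.58 ± 0.13 and Iars, another synthetase, which is not in the list, one of -0.75 ± 0.16 (5 of 5 for both). These 4 genes had adjusted p = 0.275. Asns, at -0.83 ± 0.24, the cystine transporter Slc7a11, at -0.93 ± 0.23, and Atf3, at -0.73 ± 0.18, were below 0 in 5 of 5 animals. Atf4 and Ddit3 stood at -0.27 ± 0.15 and -0.09 ± 0.15, the latter at 0.01 without animal 3. Of the 32 members 0 were called over all genes tested and 19 fell adjusted over the list alone (23, 12, 13, 18 and 17 without animals 1 to 5 in turn).

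Over all genes 0 of 8320 passed with edgeR in NS_PI vs NS (smallest adjusted p 0.133), with 455 at an unadjusted p below 0.05 against 416 by chance. DESeq2 called 5, namely Cth, Iars, Nars, Slc7a1 and Trib3, and limma-voom called 2, namely Defb4 and Slc7a1. A fit without a count filter called 4, namely Ccl20 (higher), Cth, Slc7a1 and Trib3, and a fit to only these groups 27, of which 17 fell and 9 were in the PERK-ATF4 list. Without animal 1, 3 genes passed, namely Cth, Slc7a1 and Trib3, and without the NS_PI library of animal 1 Cth alone. Defb4 and Ccl20 were named after their values were seen. The 95% interval excluded a 2-fold change for 87.8% of genes. Immediate-early genes (median -0.29; camera adjusted p = 3.49e-06; adjusted p = 0.282 with an estimated correlation; 0 fell over all genes and 2 adjusted over the list alone) were lower as a list. Small upward shifts were called for ATF6 and XBP1 targets (median 0.08; camera adjusted p = 0.0415; adjusted p = 0.957 with an estimated correlation), cholesterol synthesis (0.08; 0.0473; adjusted p = 0.705 with an estimated correlation) and airway markers (0.30; 0.0473; adjusted p = 0.258 with an estimated correlation). They had 0, 0 and 1 members called adjusted over the list alone and 0 over all genes. Those 3 calls were lost without animal 4 (adjusted p = 0.109, 0.485 and 0.109) or animal 5 (0.181, 0.494 and 0.256), and the airway call also without animal 3 (0.153). Ranges over their alternatives were 0.00670 to 0.957, 0.00598 to 0.705 and 0.00673 to 0.322.

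**Figure D4:**
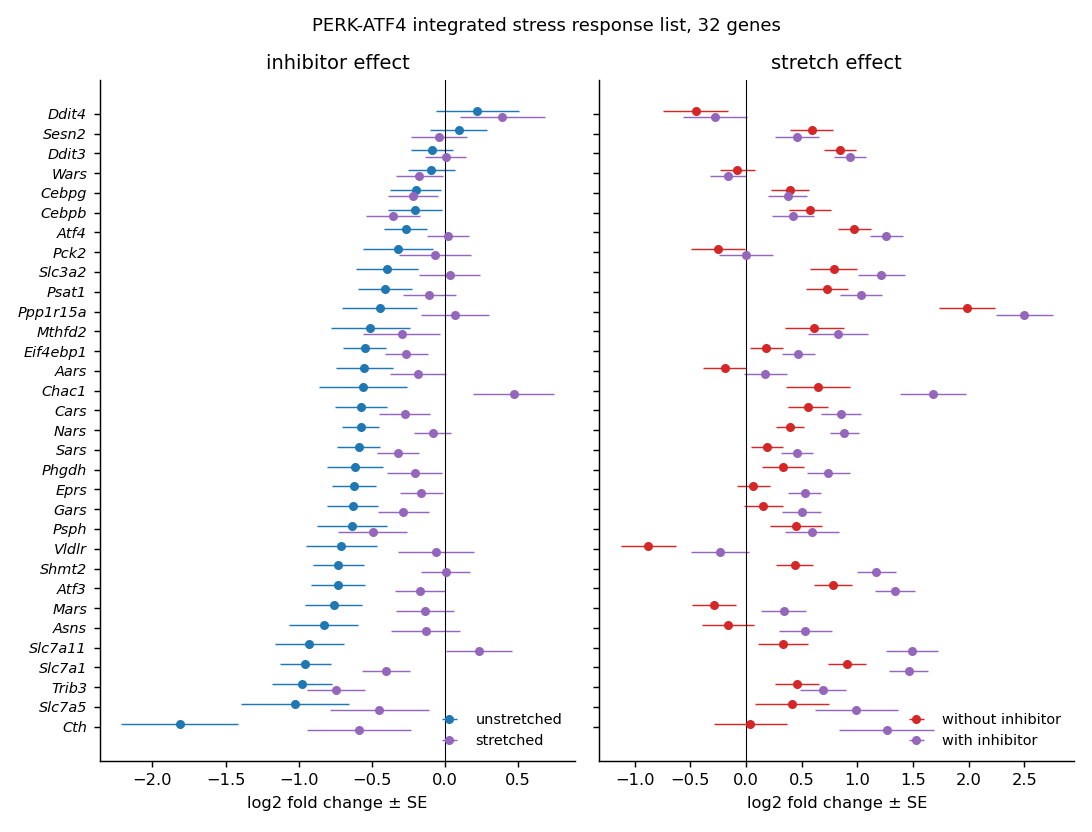
Log2 fold changes ± SE of the 32 measured PERK-ATF4 targets for the inhibitor (left, unstretched and stretched cells) and for stretch (right, without and with inhibitor), in order of the inhibitor effect in unstretched cells. Of the 32 genes, 30 lay below 0 for the inhibitor in unstretched cells and 24 in stretched cells.

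S_PI vs S asked what the inhibitor changes in stretched cells. The PERK-ATF4 list was lower with inhibitor, with 24 of 32 members below 0 and a median of -0.17 (camera adjusted p = 0.00319; adjusted p = 0.733 with an estimated correlation). Of its members 0 were called over all genes and 1 fell adjusted over the list alone. That call was lost without animal 5 (adjusted p = 0.141; 0.00194 to 0.767 over its alternatives). Trib3 had a log2 change of -0.75 ± 0.20, from 109.0 ± 43.5 to 69.3 ± 34.6 CPM, below 0 in 5 of 5 animals, with -1.63 in animal 1 and -0.67 to -0.31 in the others. Slc7a1 and Sars, seryl transfer RNA synthetase, had -0.40 ± 0.17 and -0.32 ± 0.14, and Sars stood at -0.70 in animal 5 and at -0.29 to -0.15 in the others. The genes with the smallest p were Fzd1, a Wnt receptor, with 0.76 ± 0.18, the metallothionein Mt2A with 0.69 ± 0.17, Kntc1, a kinetochore gene, with 1.12 ± 0.29, Trib3, and the class I antigen gene RT1-CE14 with -0.95 ± 0.26. Each lay on 1 side of 0 in 5 of 5 animals. Over all genes 0 of 8320 passed with edgeR (smallest adjusted p 0.999; 340 at an unadjusted p below 0.05), 0 with DESeq2 and 0 with limma-voom. The 95% interval excluded a 2-fold change for 86.1% of genes. Transitional markers were lower with inhibitor in 5 of 5 animals, by a mean of -0.14 ± 0.14 (SD; camera adjusted p = 0.155). The share of records outside annotated genes was also lower in 5 of 5, by 1.83 percentage points, and that of records aligned to several places higher, by 3.83 points (exact paired permutation p = 0.0625 for each, the smallest that 5 animals allow). Fibroblast and smooth muscle markers were higher as a list (median 0.15; camera adjusted p = 0.0431; adjusted p = 0.733 with an estimated correlation), with a mean higher by 0.22 ± 0.07 (SD) in 5 of 5 animals and 0 members called over all genes or adjusted over the list alone. The list call was lost without animal 3, 4 or 5 (adjusted p = 0.0789, 0.283 and 0.141; 0.00266 to 0.746 over its alternatives).

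The interaction asked whether the stretch response differs with the inhibitor. Across 8320 genes the stretch effects with and without inhibitor correlated with r = 0.841 and rho = 0.811, with slopes of 0.94 (effect with inhibitor on that without) and 0.75 (the reverse). Their SD over genes was 1.12 times as high with inhibitor. Of the called genes 752 rose and 716 fell in both comparisons, against 158 and 158 by chance, and 0 went in opposite directions. Of 3813 genes with an average stretch effect, 60.2% had a larger effect with inhibitor, with a median difference of 0.07. That selection counted the 2 stretch pairs of each animal as independent. Of the selected genes 617 were also called for a stretch effect that differs between animals. The stretch effect on PERK-ATF4 targets was larger with inhibitor, by a median log2 difference of 0.36 with 28 of 32 members above 0 (camera adjusted p = 1.61e-09; adjusted p = 0.417 with an estimated correlation). That on immediate-early genes was also larger, by 0.23 (camera adjusted p = 0.00673; adjusted p = 0.7099 with an estimated correlation). Of their 32 and 34 members 0 passed the interaction test, over all genes or adjusted over the list alone, and 6 PERK-ATF4 members passed the latter without animal 1. The immediate-early call was lost without animal 3 (adjusted p = 0.220; 8.14e-07 to 0.943 over its alternatives), and the median of the PERK-ATF4 list was 0.54 without animal 1 and 0.21 without animal 2 or animal 3. Gene by gene, the interaction equals the inhibitor effect in stretched cells minus that in unstretched cells. The PERK-ATF4 list was lower with inhibitor in unstretched cells (median -0.57) and less so in stretched cells. Its larger stretch effect with inhibitor thus started from a lower unstretched level.

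Slc7a11 had an interaction of 1.16 ± 0.32, Chac1, an enzyme of glutathione breakdown, 1.03 ± 0.41, Shmt2, a mitochondrial enzyme of serine metabolism, 0.73 ± 0.24 and Nars 0.49 ± 0.18, all above 0 in 5 of 5 animals. Among the genes with the smallest p were Desi2 (0.87 ± 0.21), Osbpl11 (1.21 ± 0.31), Kntc1 (1.48 ± 0.39) and Kpnb1 (1.301 ± 0.34), each above 0 in 5 of 5 animals. With edgeR, 0 of 8320 genes passed the interaction test (smallest adjusted p 0.984; 345 at an unadjusted p below 0.05), 0 with DESeq2 and 0 with limma-voom. Among the 3813 genes with an average stretch effect 0 passed (smallest adjusted p 0.928; 179 unadjusted). The 95% interval excluded a 2-fold difference for 63.9% of genes. Differences between animals in the stretch response had no term in the fit, so they stayed in the spread of this test. Those alike with and without inhibitor cancel within each animal in the interaction, so this spread can be too wide.

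**Figure D5:**
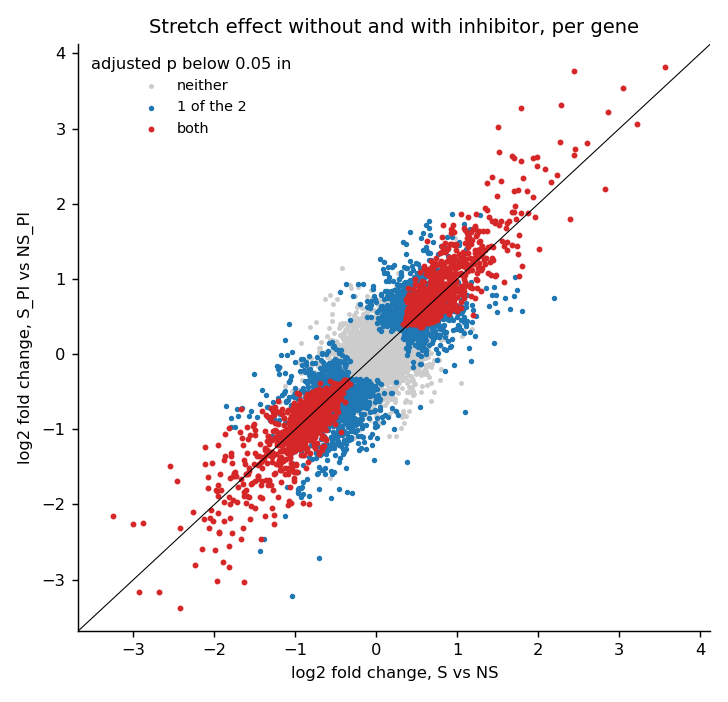
Log2 fold change with stretch of each of 8320 genes without inhibitor (x axis) and with it (y axis), coloured by adjusted p below 0.05 in both, 1 or neither comparison, with the line of equal effects. The values correlated across genes with r = 0.841.

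Averaged over stretched and unstretched cells, an effect added after seeing the data, the inhibitor changed 2 genes, both lower. Trib3 fell by 0.86 (adjusted p = 0.0425) and Slc7a1 by 0.68 (adjusted p = 0.0480). The PERK-ATF4 list had a median of -0.38 with 30 of 32 members below 0. That list call held with an estimated correlation (camera adjusted p = 0.0188). Of its 32 members 2 fell over all genes and 17 adjusted over the list alone. Lower by camera were also immediate-early genes (median -0.17; camera adjusted p = 8.82e-05; adjusted p = 0.485 with an estimated correlation) and transitional markers (-0.13; 0.0202; adjusted p = 0.530 with an estimated correlation). Higher were ATF6 and XBP1 targets (0.07; 0.00138; adjusted p = 0.665 with an estimated correlation) and fibroblast and smooth muscle markers (0.23; 0.00411; adjusted p = 0.251 with an estimated correlation). In these 4 lists 0 members passed over all genes, and 2, 1, 1 and 0 adjusted over the list alone. The 4 calls were also lost with fry. The transitional and fibroblast calls were lost without the animal as a block (0.111 for each), and the fibroblast call without animal 4 (0.0772). Ranges over their alternatives were 2.02e-07 to 0.485, 0.0165 to 0.530, 0.000215 to 0.665 and 0.000558 to 0.349. Both genes lost their call without animal 2 (adjusted p = 0.437 and 0.472), 3 (0.245 and 0.421), 4 (0.166 for each) or 5 (0.306 for each), with ranges over their alternatives of 0.000116 to 1.00 and 0.000253 to 0.472. DESeq2 called 7 genes and limma-voom 0.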

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

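The tests chosen only after the result was seen were those of animal by stretch with its alternatives, of epithelial cell loss as the whole or a part of its cause, and of leukocytes as the whole cause of the inflammatory rise. Thinned counts were also added after seeing the data. Tests of swapped labels, of cell mix, of hidden 2-fold changes and of leukocyte against fibroblast markers were not among those fixed beforehand. For the PERK-ATF4 list, the limits for cell mix and depth were set from its observed median. Camera with an estimated correlation was planned, and its use to weigh the inhibitor's effect on the PERK-ATF4 list was chosen afterwards.

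The response to stretch differed between animals, with 1192 of 8320 genes called by an edgeR test of animal by stretch against at most 2 in 3 simulations without such an effect (2462 at an unadjusted p below 0.05). The stretch changes of animal 1 had the highest SD over genes (0.862; 0.561 to 0.700 in the others) and the lowest correlation with the mean of the other animals over the 3813 genes with an average stretch effect (0.784; 0.799 to 0.848). It had falls in Epcam (log2 change of -2.51), Cdh1 (-2.43), Cldn7 (-2.76), Ocln (-2.38) and Spint1 (-2.65) and rises in Sgk1 (3.04), Ccl7 (2.85) and Inhba (4.01), genes chosen after their values were seen. The number of genes called moved most without animal 2, to 504, and was 718 without animal 1. The tables argue against depth, since 857 genes were called after thinning to the smallest library, and against swapped labels in animal 1, since 85.4% of the genes called without it went the same way in its pair without inhibitor and 86.7% in that with inhibitor. A smaller share of epithelial cells as the whole cause cannot be told apart from other causes. Against the mean of the other animals, 52 epithelial genes lay lower in animal 1 by a median of 0.77, with an SD over genes of 0.98, which is 1.47 times the highest of the other animals (0.54 to 0.67). Nor can a smaller share of epithelial cells as a part of the cause. Against that mean, markers of fibroblasts, leukocytes and mesothelium were higher in animal 1, by 0.41 ± 0.19, 0.21 ± 0.13 and 0.62 ± 0.39 (SE over 11, 15 and 3 markers), and the 4 endothelial markers lower, by 0.58 ± 0.34. Over these 33 markers the types differed by an F test (p = 0.0292, n = 33 genes), and a rank test did not pass (p = 0.0723, n = 33 genes). Unstretched cells of animal 1 without inhibitor also differed in marker means (log2 CPM). Mesothelial markers stood at 6.75 (5.46 to 5.80 in the others) and type I markers at 7.66 (5.28 to 7.23). Airway markers stood at 3.51 (4.41 to 5.19) and leukocyte markers at 4.85 (5.63 to 6.37). Type II, fibroblast and endothelial markers lay within the range of the others. How this bears on the stretch response was not tested. No biological explanation was tested, since the labels give no feature that sets the animals apart.

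The PERK-ATF4 list was lower with the inhibitor in unstretched cells, by a median of -0.57, while 0 genes passed over all genes with edgeR (455 at an unadjusted p below 0.05; DESeq2 5, limma-voom 2). The tables argue against depth, since the median was -0.56 after thinning. They also argue against a shift among cell types with at least 10 measured markers as the whole cause. Among these types the median farthest from 0 was -0.19, for transitional cells. Types with fewer measured markers were left out of this test, so it cannot exclude a shift in them. The median of the 4 airway markers was 0.30, past the limit set for the larger lists, and their mean was higher in 5 of 5 animals. The 95% interval excluded changes of 2-fold or more for 87.8% of genes, and for the rest such changes hidden by the spread cannot be told apart from none, since the interval includes them. An effect of the inhibitor on this list beyond other lists, the design's treatment, is a candidate explanation, since the list was lower with an estimated correlation too (camera adjusted p = 0.0112). It was found and tested on the same libraries.

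Leukocyte markers and inflammatory genes were both higher with stretch, the markers by a mean of 0.39 in S vs NS. The tables argue against depth, since the marker mean rose by 0.399 after thinning. More leukocytes as the whole cause cannot be told apart from other causes. The mean of all 28 inflammatory genes exceeded that of the 15 markers by 0.0571 ± 0.187 (SE), with medians of 0.46 and 0.47. The genes spread more widely (SD 0.89 and 0.32), and rises and falls cancel in their mean. Of the 10 that rose, 7 rose more than Fcer1g, the marker with the largest rise (0.91), while Csf1 and Irf1 fell. Those 7 were picked by their rise, so they do not settle the cause for the whole list. A smaller share of epithelial cells, which would raise all other types alike, cannot be told apart from a change in leukocytes, since leukocyte markers rose more than fibroblast markers in 7 of 10 within-animal pairs. Averaged over both inhibitor states, leukocyte markers changed by 0.36 to 0.60 per animal and fibroblast markers by -0.10 to 0.51. Endothelial markers changed by -0.82 to -0.08, which goes against a rise of all types alike but rests on 4 markers. Epithelial lists did not move alike. In animals 2 and 3 leukocyte markers rose by 0.36 and 0.38, while type II markers changed by 0.12 and 0.24. Junction genes changed there by 0.07 and 0.05 and type I markers by -0.47 and -0.14. In animals 4 and 5 junction genes changed by -0.64 and -0.60. An effect of stretch on gene expression in the cells themselves stays open, as does one on leukocyte numbers, and neither was tested.

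The stretch effect differed with the inhibitor for 2 lists by camera on the interaction, by a median of 0.36 for PERK-ATF4 targets (adjusted p = 0.417 with an estimated correlation) and of 0.23 for immediate-early genes (adjusted p = 0.7099 with an estimated correlation). The PERK-ATF4 list was lower with inhibitor in unstretched cells (median -0.57) and less so in stretched cells. Msln in S vs NS stood at 2.30 in animal 1, far from the others at 0.19 to 0.48. Trib3 in S_PI vs S stood at -1.63 in animal 1, far from the others at -0.67 to -0.31. Sars in S_PI vs S stood at -0.70 in animal 5, far from the others at -0.29 to -0.15. Tnfaip6 in S_PI vs NS_PI stood at 5.10 in animal 1, far from the others at 2.13 to 2.52. In all, 197 groups of 5 values were examined for a far value, of which chance gives 9.85 and 4 had one, 3 of them in animal 1. Outside the annotated genes, records made up 16.2% of all records in the library with the lowest share and 24.5% in that with the highest.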

How the results depend on the processing

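The tests chosen only after the result was seen were the average effects of stretch and of the inhibitor, animal by stretch, limma-voom for the interaction among stretch-responsive genes, and thinned counts. No gene called in the edgeR fit and named in the text got the opposite sign under any alternative compared for named genes. Signs of named genes were not compared with a single library left out or with thinned counts. Of 139 named-gene results, 132 kept direction and side of the threshold with DESeq2, 136 with limma-voom, 138 with median-ratio and with upper-quartile scaling, 137 with library size alone, 136 without a filter, 138 with at least 5 CPM in 5 libraries, 117 of the 128 run with only the compared groups, 130 to 134 without 1 animal and 106 without the animal as a block, where 32 dropped below the threshold. Counts in S_PI vs S and the interaction were 0 under every alternative run. S vs NS gave 1418 to 1784 genes without 1 animal and 1398 to 2224 without 1 library, S_PI vs NS_PI 1839 to 2453 and 2072 to 2907. Thinned counts gave 1529, 2013 and, for the average stretch effect, 3129 genes of 7481 tested, with fewer genes and counts by construction. Depth limits genes near 0.958 to 3.00 CPM, and a 2-fold interaction was recovered for 38.1% of simulated genes and a 1.5-fold one for 6.09%.

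Without the animal as a block, S vs NS gave 818 genes, S_PI vs NS_PI 1229, the average stretch effect 2435 against 3813 and the average inhibitor effect 0 against 2; a 1.5-fold minimum gave 2065 for average stretch, by construction. With only the compared groups, S vs NS gave 1048, S_PI vs NS_PI 2160 and NS_PI vs NS 27. These fits take the spread from the compared groups alone, with fewer residual degrees of freedom. NS_PI vs NS also gave 5 with DESeq2, 2 with limma-voom, 4 without a filter, 0 to 3 without 1 animal and 0 to 1 without 1 library. The average inhibitor effect gave 7 with DESeq2, 0 with limma-voom, 4 without a filter, 1 with thinned counts, 0 to 4 without 1 animal and 0 to 3 without 1 library. Animal by stretch gave 504 to 1194 without 1 animal, 1260 with limma-voom, 1199 with median-ratio scaling and 1195 with at least 5 CPM. The correlation of the stretch effects was 0.803 to 0.838 without 1 animal. Lists called in S vs NS were 6 without the block, 1 with an estimated correlation, 16 with fry and 9 to 13 without 1 animal; in NS_PI vs NS 1, with an estimated correlation and with fry, and 2 to 7; in S_PI vs S 1 without the block, 0, 0 and 0 to 4; in S_PI vs NS_PI 7, 2, 18 and 9 to 13; in the interaction 0, 0 and 1 to 4; for average stretch 1, 19 and 11 to 13; for the average inhibitor effect 3 without the block, 1, 1 and 4 to 7. Signs turned for values that had not passed. Xbp1, S vs NS, was 0.040 without the block, 0.0037 with DESeq2, 0.0055 with median-ratio scaling, 0.0061 with at least 5 CPM, 0.19, 0.10 and 0.05 without animals 2, 3 and 5, and -0.33 to 0.19 without 1 animal. Asns, S vs NS, was 0.15 and 0.017 without animals 2 and 3 (-0.35 to 0.15 without 1 animal), Sftpc, S vs NS, 0.043 without animal 1 (-0.60 to 0.043), and Ddit3, NS_PI vs NS, 0.0073 without animal 3 (-0.18 to 0.0073). Where no construction is named, the cause was not tested.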

Other observations

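The test of opposite effects of stretch and inhibitor was chosen only after the result was seen.

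Mean markers of some cell types moved the same way in 5 of 5 animals. Airway markers were higher with the inhibitor in unstretched cells in 5 of 5 animals, by 0.40 ± 0.20 (mean and SD of paired log2 differences), and endothelial markers were lower with stretch in the presence of the inhibitor in 5 of 5 animals, by -0.47. Type I markers were lower with stretch in 5 of 5 animals both without inhibitor, by -0.57 ± 0.47, and with it, by -0.83 ± 0.71, and averaged over both pairs the change was -1.66 in animal 1 and -0.66 to -0.14 in the others. Transitional markers were lower with the inhibitor in 5 of 5 animals, by -0.15 in unstretched and -0.14 in stretched cells. Each of these has the smallest two-sided exact paired permutation p that 5 animals allow, 0.0625.

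Splits of the libraries were counted in fits to the 10 libraries of each comparison alone, and for the interaction in fits to the 10 within-animal pairs. In the fits to 10 libraries, with the animal as a block, a split that parts 1 or 3 animals compares those animals alone. Most of the 100 drawn are of that kind. Splits that part all 5 animals, as the real ones do, are too few for a share under 0.05. In S vs NS the real split gave 1048 genes and the highest of the others drawn 292 (1 of 100 as large), and in S_PI vs NS_PI 2160 and 31 (1 of 100). The other 8 drawn splits that part all 5 animals gave at most 0, 1, 0, 0 and 0 genes in the order S vs NS, NS_PI vs NS, S_PI vs S, S_PI vs NS_PI and interaction. For NS_PI vs NS the fit to 10 libraries gave 27 genes and the highest other split 14 (1 of 100), but the edgeR fit to all 20 libraries called 0 (455 at an unadjusted p below 0.05; DESeq2 5, limma-voom 2), so these splits do not bear on the count reported. With 0 genes in S_PI vs S and in the interaction (340 and 345 at an unadjusted p below 0.05 in the edgeR fit to all libraries; 0 with DESeq2 and limma-voom), each of the 100 splits is as large by definition, which decides nothing about chance. Their highest other splits gave 1019 and 109 genes. With the animal as a block, that with 1019 genes compares the libraries of animal 1 alone. The interaction fits had the pair as the block and not the animal. The split with 109 genes, which parts animal 4, thus also compares the stretch effects of the other animals with each other. The 4 other splits of the interaction that part animal 4 alone gave 0.

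The effects of stretch and of the inhibitor had, with no library in both, a mean covariance across genes below 0 for the inhibitor in unstretched cells and above 0 for that in stretched cells. S vs NS and NS_PI vs NS share the unstretched libraries, which alone gives a positive covariance of 0.0286 in simulations, and the observed covariance was -0.0051. With the animals divided so that no library served both, the mean covariance was -0.0215, below 0 in 19 of 20 divisions, so a shared effect of opposite sign, beyond the shared unstretched libraries, may exist and was not settled by this test. For S vs NS with S_PI vs S, which share the stretched libraries, the same division gave a mean of 0.00825 and 0 of 20 below 0, so the sign of the covariance was not shared by the 2 inhibitor comparisons.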
